A study of Mus musculus with 10 samples.

How the data were processed

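Portal tracts of 1-week-old mouse livers were captured by laser microdissection from frozen sections, 12 to 20 tracts per replicate, and RNA was isolated with the PicoPure kit and treated with DNase, per the labels' protocols. Biotin-labelled cDNA was hybridized to single-colour arrays. The labels name 5 samples as control and 5 as Jag1+/-Rfng+/-, and give the strain of the controls as C57Bl/6J. Groups and replicate numbers were taken from the sample titles. How the tracts were chosen, beyond their being portal tracts, is not given in the sources used here.

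The log2 expression values were deposited by the authors, with 1 value per probe set and array for 33649 probe sets, ranging from 1.08 to 12.47. RMA and Partek 6.6 are named for them, with no role or order, per the submitters' processing notes. RMA usually corrects background, equalizes the distributions of the arrays and summarizes the probes of a set on a log2 scale, which compresses the folds of dim genes. Scanner output was not used here, so no detection call or signal over background per probe was at hand. The table held 0 columns of no sample. Gene symbols came from the array's platform annotation, in which 23521 probe sets have 1 gene symbol, 1814 several and 8314 none. Only probe sets with 1 symbol were used, and 23328 of them matched a RefSeq gene by Entrez identifier in the GRCm38.p6 assembly table, which left 193 unmatched. That table gave chromosomes and gene order for 21991 genes. The build behind the array annotation is not given in the sources used here, so no coordinates are printed. For the 1082 genes with several probe sets, the set with the highest mean over the 10 arrays was taken, which gave 22180 genes. Genes without such a probe set were not analysed here.

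The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend, no covariate, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A looser description counts genes at an unadjusted p under 0.05 with at least 1.5-fold difference. The targeted genes were also compared with an exact permutation test of the difference of means over all 252 splits of the 10 arrays, two-sided. No filter on dim probe sets was used. No pair of arrays held identical values (0 pairs).

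For gene groups, 35 lists with 955 entries, 887 of them measured, were fixed before the data were examined. They cover Notch receptors, ligands and modifiers, Notch targets, biliary epithelium, tubules and primary cilium, cell types that the capture could hold, matrix, signalling pathways, cell cycle, metabolism, inflammation and housekeeping processes. Each was tested with limma's camera, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of at least 5 measured members. Camera with a correlation estimated for each list and limma's fry were alternatives. With the estimated correlation 0 lists passed, and 0 had an unadjusted p under 0.05. For fry's directional test 0 lists passed, with a lowest adjusted p of 0.618, and for its test of change in either direction 3 did. The mean of each list per array was also compared with the exact permutation test. Members past 0.05 were counted both adjusted over all genes and adjusted over the list alone.

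Around Jag1 and Rfng, the share of genes with an unadjusted p under 0.05 was taken among the 50 tested genes on either side in the reference order and set against all windows of the genome with as many genes. The plan set both loci against windows of 100 genes, but Rfng has only 76 such neighbours, so windows of 76 genes were used for it, a change made after the data were seen. Under a block, covariates, weights and other eBayes settings, where the exact test was not used, the unadjusted p of Jag1 and Rfng was compared with that of the fit without these settings.

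The genes named follow a rule fixed before the data were examined. It takes Jag1 and Rfng, then up to 10 higher and 10 lower genes past the adjusted threshold, filled to 10 per direction by the lowest unadjusted p among genes with at least 1.5-fold difference, which are given as values. It then takes the 4 members with the lowest unadjusted p of each list past its test and of the Notch, Notch target and biliary lists. Predicted genes, small RNAs, olfactory, vomeronasal and taste receptors, rearranging immune receptor segments and sex-linked genes were counted but not named in the second step. The rule gave 65 genes.

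Alternatives were leaving out each array, a replicate block, the 7 arrays with the shared sample-name number (3 control and 4 Jag1+/-Rfng+/-), array weights, eBayes with trend and robust, quantile, median and cyclic loess normalization, genes above the median level (3.74), the mean of a gene's probe sets, all probe sets, the hepatocyte list or a sex score as covariate, and other window sizes. Added after the data were seen were those arrays without Jag1+/-Rfng+/- replicate 5 and the portal fibroblast list as covariate. The same results were computed for 100 of the 126 splits of the 10 arrays into groups of 5, the real split included. Figures were drawn with matplotlib 3.10.9, and tables were prepared with Python 3.11.15 and pandas 2.3.3.

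The procedure was tested on simulated data with the means and spreads of the 22180 genes, 5 arrays per group and 200 genes changed. It recovered 29.9% of genes changed 1.5-fold, 70.1% of genes changed 2-fold and 100% of genes changed 4-fold, and called 11 unchanged genes. These arrays were simulated as independent genes, without the shared variation between real arrays. The adjusted threshold also loosens as more genes pass. With 200 genes changed, against 2 genes past the threshold in the real comparison, the shares recovered do not carry over to it.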

Results

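Portal tracts are the regions of the liver in which a bile duct runs beside branches of the portal vein and the hepatic artery, wrapped in portal fibroblasts and matrix. The data are gene expression values of portal tracts cut by laser capture from frozen liver sections of 1-week-old mice, with 12 to 20 tracts collected per replicate. RNA from 5 control and 5 Jag1+/-Rfng+/- samples was measured on 10 single-colour arrays. Jag1+/-Rfng+/- mice are heterozygous at Jag1, which encodes a ligand of the Notch receptors, and at Rfng, which encodes Radical fringe, a glycosyltransferase that modifies Notch. The comparison asks how duct remodelling and cell differentiation in the tracts differ between these mice and controls.

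Array data have no read depth, and the number of arrays limits their precision. The array medians lay between 3.22 and 3.30 on the log2 scale, and the correlation across probe sets between pairs of arrays ranged from 0.956 to 0.987. Jag1+/-Rfng+/- replicate 5 stood apart, with correlations of 0.956 to 0.963 with the other arrays, against at least 0.969 among the other 9. Its sample name carries the suffix excl, whose meaning is not given, and it was kept. Each sample has its own name, but no label says that each is a separate mouse, so the p-values measure the spread between these samples. Xist was high, and the Y-linked genes Eif2s3y, Kdm5d and Uty low, on 2 arrays of each group. On these arrays the Y-linked genes read 1.82 to 2.84, and on the other 6 Xist read 2.25 to 2.91, so a gene that is absent can read 1.82 to 2.91.

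The signals of both targeted genes were lower in the Jag1+/-Rfng+/- arrays. Rfng (probe set 17273316, chromosome 11) averaged 4.82 ± 0.20 in controls and 4.36 ± 0.16 in Jag1+/-Rfng+/- (log2, SD, n = 5 each), 1.37-fold lower, and the groups did not overlap (exact permutation p = 0.00794, two-sided, the smallest that 5 against 5 arrays can give). Jag1 (probe set 17392151, chromosome 2) averaged 5.72 ± 0.93 and 4.39 ± 0.63, 2.51-fold lower, but controls 4 and 5 read 4.59 and 4.90, within the Jag1+/-Rfng+/- range of 3.68 to 5.06, and the exact permutation p was 0.0556. Without control replicate 4 the Jag1 difference was -1.61 log2 (exact permutation p = 0.0159), and without control replicate 5 it was -1.53 (exact permutation p = 0.0476). Leaving out any other single array gave differences of -1.5 to -1.11, and none passed 0.05 (exact permutation p = 0.0556 to 0.0952). Adjusted over all genes in the limma fit, neither passed (adjusted p = 0.559 for Jag1 and 0.416 for Rfng). Jag1 was highest on controls 2 and 3 (6.59 and 6.57), where the portal fibroblast list averaged 0.23 and 0.35 relative to the control mean. It was lowest on Jag1+/-Rfng+/- replicates 1 and 5 (3.75 and 3.68), with that list at -0.94 and -0.91. At list means of 0.03 and 0.04, control 1 read 5.95 and Jag1+/-Rfng+/- replicate 4 read 5.06. Whether fibroblast content has a part in the Jag1 fold was not tested. The type of either mutant allele is not given, so the probes may lie outside the deleted part and a lower signal is not a firm check of the labels. The sample names hold 4 different numbers of unstated meaning, a possible batch. Among the 7 arrays that share the only number found in both groups (3 control and 4 Jag1+/-Rfng+/-), Jag1 differed by -1.37 (exact permutation p = 0.171) and Rfng by -0.38 (exact permutation p = 0.0571). The other numbers hold 1 array each, too few for a value.

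Slpi rose and Mme fell in Jag1+/-Rfng+/- portal tracts, and these were the 2 genes of 22180 tested that passed an adjusted p of 0.05. Slpi, which encodes a secreted inhibitor of leukocyte proteases, rose by 2.35 ± 0.17 log2 (SE), 5.10-fold, from 5.58 ± 0.35 in controls to 7.93 ± 0.25 (SD, n = 5 each; limma adjusted p = 0.000331; probe set 17394153, chromosome 2). Mme, which encodes the membrane metalloendopeptidase neprilysin, fell by 2.09 ± 0.19 log2 (SE), 4.25-fold, from 5.20 ± 0.35 to 3.11 ± 0.31 (SD, n = 5 each; limma adjusted p = 0.00141; probe set 17397990, chromosome 3). For both genes all 5 arrays of each group lay apart from the other group. On Jag1+/-Rfng+/- replicates 1 and 4 Mme read 2.78 and 2.85, within the range of absent genes, so the size of its fall is not bounded. Within the 7 arrays with the shared sample-name number Slpi differed by 2.24 (limma adjusted p = 0.0423) and Mme by -2.17 (limma adjusted p = 0.0145). Without replicate 5 these arrays, 3 against 3, ended both calls: Slpi differed by 2.16 (limma adjusted p = 0.134) and Mme by -2.12 (limma adjusted p = 0.0566), and limma called 0 genes, with 1215 at an unadjusted p under 0.05. The count of genes past the threshold was 5 without control replicate 4, 4 without control replicate 5 and 6 without Jag1+/-Rfng+/- replicate 2.

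**Figure D1:**
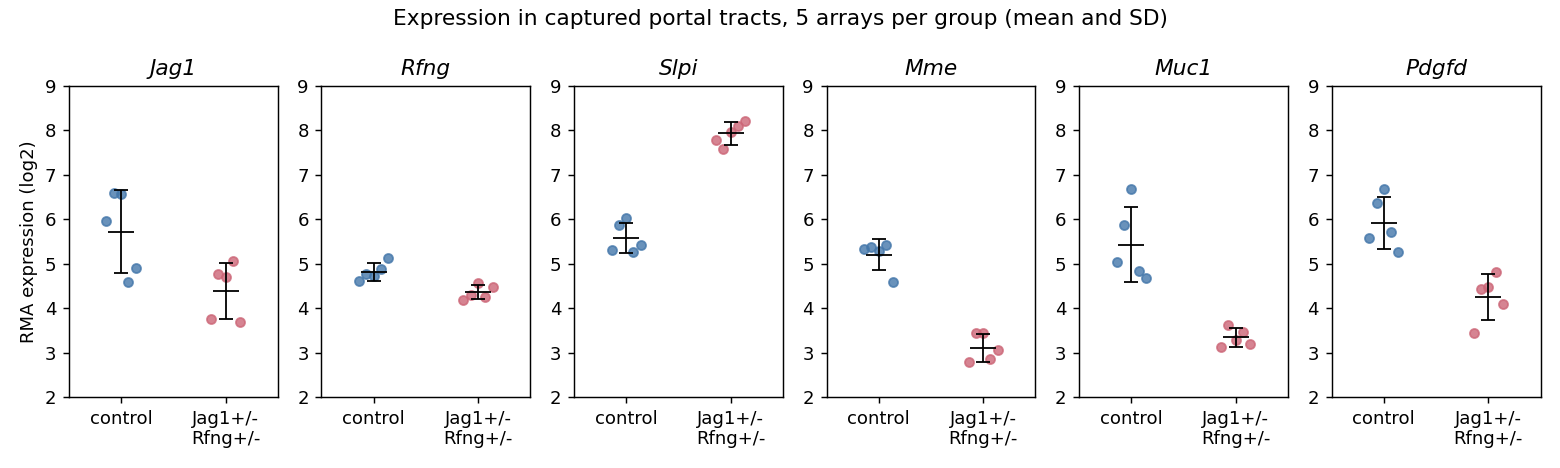
Expression of 6 genes on each array (vertical axis, RMA log2 values) in control and Jag1+/-Rfng+/- portal tracts; points are the 5 arrays of a group, the long bar is the mean and the error bar the SD. Slpi averaged 5.58 in controls and 7.93 in Jag1+/-Rfng+/-, Mme 5.20 and 3.11, and the Jag1 values of the groups overlap.

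At the looser threshold of 0.1, 12 genes had a lower adjusted p, 3 higher and 9 lower, Slpi and Mme included. Among genes given here as values only, Muc1, a membrane mucin of epithelia, was 4.22-fold lower (limma adjusted p = 0.0745), Gabrp 3.33-fold lower (0.0745), Tmem45a 2.80-fold lower (0.0620), Ugt8a 2.75-fold lower (0.0745) and Akr1c18, a hydroxysteroid dehydrogenase, 2.44-fold lower (0.0745). Osgin2, Eola1 and the succinate receptor gene Sucnr1 were 1.96-fold, 2.12-fold and 1.73-fold lower (0.0745 each), Sucnr1 at a control mean of 2.54, within the range of absent genes. Gabrp on Jag1+/-Rfng+/- replicates 1, 3 and 5 (2.83 to 2.88) and Eola1 on replicates 3 and 5 (2.83 and 2.75) also read within it. So did Ugt8a on Jag1+/-Rfng+/- replicate 1 (2.70), so the folds of Gabrp, Eola1 and Ugt8a are not bounded. On the other side Lrg1, a secreted glycoprotein, read 1.79-fold higher (0.0620), Rdh16, a retinol dehydrogenase, 2.90-fold (0.108), Tnfrsf12a, the receptor of the cytokine TWEAK, 1.87-fold (0.189), and Tff3, a trefoil peptide of mucus-secreting epithelia, 3.51-fold (0.217). Cit, Ifi27l2b, Osbpl3 and the efflux transporter gene Abcc3 were 1.64-fold to 2.00-fold higher, with adjusted p between 0.253 and 0.289, Ifi27l2b from a control mean of 2.67, also within that range. Ahcy read 2.77-fold higher (0.0577) on the brighter of its 2 probe sets (controls 5.22 to 5.58, Jag1+/-Rfng+/- 6.32 to 7.36) and lower on the other (controls 4.44 to 5.98, Jag1+/-Rfng+/- 4.12 to 4.37), so its direction is uncertain. At an unadjusted p under 0.05, 1500 genes differed, 660 higher and 840 lower, where 1109 are expected by chance, and 332 of them also differed at least 1.5-fold, 99 higher and 233 lower.

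Genes of the biliary epithelium moved in both directions. Of 30 measured members of the list, 11 passed an adjusted p of 0.05 adjusted over the list alone, 8 lower and 3 higher, and 0 adjusted over all genes. Muc1 fell by 2.08 ± 0.33 log2 (SE) and Pdgfd, a platelet-derived growth factor, by 1.67 ± 0.30. Ehf, an epithelial ETS transcription factor, fell from 4.68 ± 0.77 to 2.82 ± 0.29 (SD, n = 5 each), a level within the range of absent genes, so the size of its fall is not bounded. For these 3 genes the groups lay apart on all arrays. The keratin genes Krt7 and Krt19 fell 1.68-fold and 1.69-fold, the cell adhesion gene Epcam 1.69-fold, Prom1 1.64-fold and the transcription factor gene Onecut1 1.40-fold. In contrast the tight junction genes Cldn6 and Cldn7 rose 2.36-fold and 1.74-fold, and Krt23, another keratin, rose 1.71-fold. Of these, 7 (Krt7, Krt19, Epcam, Onecut1, Prom1, Cldn6 and Cldn7) lie outside the rule for named genes and were named after their values were seen. The list as a whole lay lower by a mean of 0.31 log2, with 20 members lower and 10 higher (camera adjusted p = 0.00105, and adjusted p = 0.711 with an estimated correlation), while fry's test for change in either direction gave an adjusted p of 0.00283. An exact permutation test of the list's mean per array did not pass (p = 0.135). The portal fibroblast list, lower by a mean of 0.55 log2, moved with it, and with that list's mean as a covariate the biliary list averaged 0.02 (adjusted p = 0.810) and 9 members passed adjusted over the list alone. The count of 11 became 7 without control replicate 2 or 3, 5 without Jag1+/-Rfng+/- replicate 1 and 4 within the arrays with the shared sample-name number.

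**Figure D2:**
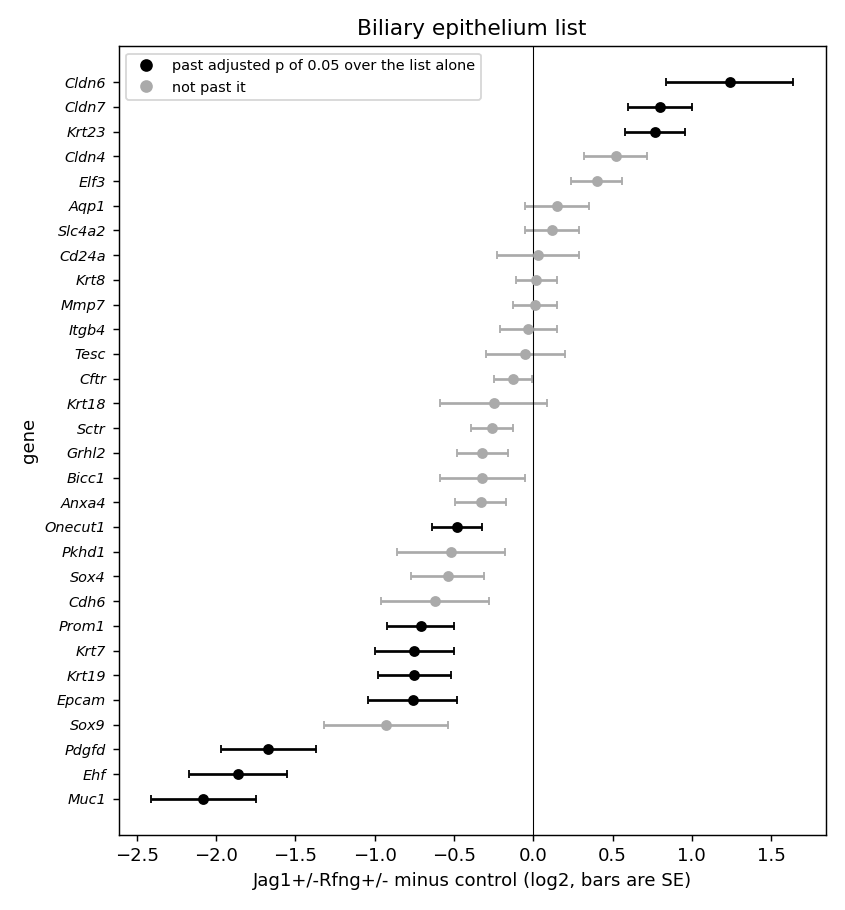
Difference between Jag1+/-Rfng+/- and control (horizontal axis, log2, 5 arrays per group) for the 30 measured genes of the biliary epithelium list (vertical axis); points are fitted differences and bars their SE. The 11 black points passed 0.05 adjusted over the list alone, from Muc1 at -2.08 to Cldn6 at 1.24.

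Markers of portal fibroblasts and of the matrix around the ducts were lower in Jag1+/-Rfng+/-. The portal fibroblast list lay lower by a mean of 0.55 log2, with 22 of 27 members lower (camera adjusted p = 1.26e-06, and adjusted p = 0.711 with an estimated correlation). In it 3 members, Pdgfra, Ogn and Thy1, fell 2.07-fold, 2.47-fold and 2.22-fold adjusted over the list alone. Eln, which encodes elastin, averaged 8.24 ± 0.60 in controls and 6.99 ± 0.87 in Jag1+/-Rfng+/- (SD, n = 5 each) and passed neither adjustment. The basement membrane list lay lower by 0.29, with 20 of 24 members lower (camera adjusted p = 1.14e-05, and adjusted p = 0.711 with an estimated correlation). The laminin chain genes Lama2 and Lamb1 and the laminin receptor subunit gene Itga6 fell 2.31-fold, 1.58-fold and 1.41-fold adjusted over the list alone. Lamc1 differed by -0.51 ± 0.18 log2 (SE). The fibrillar collagen and matrix list lay lower by 0.38, with 29 of 37 members lower (camera adjusted p = 3.53e-05, and adjusted p = 0.711 with an estimated correlation). Of its members 0 passed either adjustment, and Lum differed by -0.69, Plod2 by -0.69 and Thbs2 by -1.21 log2. This list shares 1 gene, Eln, with the portal fibroblast list. Within the 3 against 3 arrays with the shared sample-name number and no replicate 5 the matrix list averaged -0.09 (adjusted p = 0.556). With the mean of the portal fibroblast list as a covariate the matrix list turned to 0.28 (adjusted p = 1.49e-06) and the basement membrane list averaged 0.04 (adjusted p = 0.700). In an exact permutation test of list means per array none of these 3 lists passed (p = 0.0635 for portal fibroblasts, 0.103 for basement membrane and 0.222 for matrix). Over all 35 lists the lowest such p was 0.0635, or 0.528 with Benjamini-Hochberg adjustment. Without Jag1+/-Rfng+/- replicate 1 the matrix list averaged -0.25 (camera adjusted p = 0.0201). The fibroblast mean also varied among controls, from 0.35 above their average on control replicate 3 to 0.50 below on control replicate 4, and was 0.04 above it on Jag1+/-Rfng+/- replicate 4.

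The tubule and primary cilium list lay lower by a mean of 0.18 log2, with 20 of 25 members lower and 0 past either adjustment (camera adjusted p = 0.000450, and adjusted p = 0.711 with an estimated correlation). Rpgrip1l, Ift57, Bbs4 and Cc2d2a, which encode parts of the cilium and its base, differed by -0.35, -0.70, -0.30 and -0.43, Bbs4 with a Jag1+/-Rfng+/- mean of 2.88 within the range of absent genes. With the mean of the portal fibroblast list as a covariate the tubule and cilium list averaged 0.00 (adjusted p = 0.970) and the Notch receptor list described next 0.02 (adjusted p = 0.939). Without control replicate 3 the tubule and cilium list averaged -0.11 (adjusted p = 0.0390). The Notch receptors, ligands and modifiers list lay lower by 0.14, with 25 of 36 members lower, the targeted genes included, and 0 past either adjustment (camera adjusted p = 0.0489, and adjusted p = 0.711 with an estimated correlation). Besides Jag1 and Rfng, its lowest unadjusted p values belonged to Dll1, a Notch ligand (-0.40 log2), and Neurl1a, a ubiquitin ligase (0.35). Leaving out control replicate 1, 2 or 3 or Jag1+/-Rfng+/- replicate 1, 2 or 5 ended the call of this list, with adjusted p between 0.0601 and 0.378. So did quantile normalization (0.0912), cyclic loess (0.0917), trend and robust eBayes (0.0629), the sex covariate (0.0621) and the arrays with the shared sample-name number without replicate 5 (0.0984). The Notch target list did not pass (mean -0.21, 10 of 19 members lower, camera adjusted p = 0.106). Its members with the lowest unadjusted p, the transcription factor genes Heyl, Hey1 and Hey2 and the cyclin gene Ccnd1, differed by -0.92, -0.75, -0.45 and -0.70 log2 with 0 members past either adjustment. The Notch target list passed without control replicate 4 (-0.29, adjusted p = 0.00407), without Jag1+/-Rfng+/- replicate 4 (-0.26, 0.0347), with the hepatocyte covariate (-0.26, 0.0217) and among genes above the median level (-0.32, 0.0372), and averaged -0.13 without control replicate 3 (0.490).

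Lists of myeloid cells and of lipid metabolism lay higher in Jag1+/-Rfng+/-. Cholesterol synthesis genes were higher by a mean of 0.28 log2, with 18 of 19 members higher (camera adjusted p = 1.14e-05, and adjusted p = 0.711 with an estimated correlation). Of its members 0 passed either adjustment, and the enzyme genes Msmo1, Lss, Sqle and Nsdhl differed by 0.78, 0.54, 0.46 and 0.42. The fasting and fatty acid oxidation list lay higher by 0.18, with 16 of 21 members higher (camera adjusted p = 0.00884, and adjusted p = 0.711 with an estimated correlation). In it 2 genes passed adjusted over the list alone. Cidec, a lipid droplet protein gene, rose from a control mean of 2.89, within the range of absent genes, to 3.93, so its fold is uncertain, and Angptl4, an inhibitor of lipoprotein lipase, rose 1.58-fold. Cyp4a14 and Plin2 differed by 0.57 and 0.39. The fatty acid oxidation enzyme genes of the list did not rise together. Hadhb, Hadha, Acadvl and Acaa2 differed by -0.47, -0.19, -0.18 and -0.16, and Acadm, Acadl and Cpt2 by 0, 0.05 and 0.06. Ehhadh and Cpt1a differed by 0.37 and 0.13. These enzyme genes lie outside the rule for named genes and were named after their values were seen. This list did not pass without control replicate 3 (adjusted p = 0.255), without Jag1+/-Rfng+/- replicate 2 (adjusted p = 0.0618) or with the portal fibroblast covariate (-0.02, adjusted p = 0.939). The neutrophil and myeloid progenitor list lay higher by 0.28, with 18 of 24 members higher (camera adjusted p = 0.000675, and adjusted p = 0.711 with an estimated correlation) and 0 past either adjustment. The granule protease and peroxidase genes Ctsg, Prtn3 and Mpo differed by 1.31, 0.82 and 0.65 and Ms4a3 by 0.38. Other neutrophil genes of the list lay near 0 or lower: S100a8 at -0.02, S100a9 at -0.08, Camp at -0.04, Ly6g and Mmp8 at 0 and Retnlg at -0.37. Mmp9, Ltf and Cxcr2 lay at 0.38, 0.33 and 0.28. These genes lie outside the rule for named genes and were named after their values were seen. This list did not pass within the 3 against 3 arrays with the shared sample-name number and no replicate 5 (0.17, adjusted p = 0.0984). The macrophage and Kupffer cell list lay higher by 0.17, with 22 of 26 members higher (camera adjusted p = 0.000615, and adjusted p = 0.711 with an estimated correlation) and 0 past either adjustment. Clec4f, a marker of Kupffer cells, lay at 0.67, Spic at 0.42, C1qa at 0.34 and Folr2 at 0.32. It rested on Jag1+/-Rfng+/- replicate 1, without which it averaged 0.05 (adjusted p = 0.197). It averaged -0.01 within the arrays with the shared sample-name number (adjusted p = 0.777), 0.08 there without replicate 5 (adjusted p = 0.150) and 0.10 with the portal fibroblast covariate (adjusted p = 0.144).

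The erythroid list also passed (mean 0.40 log2, 24 of 25 members higher, camera adjusted p = 0.000487, and adjusted p = 0.711 with an estimated correlation), with 0 members past either adjustment. Its call rested on Jag1+/-Rfng+/- replicate 5. On that array the list stood 2.09 above the control mean, against -0.15 to 0.21 on the other 4 Jag1+/-Rfng+/- arrays. Add2, a membrane skeleton gene, read 6.55 there against at most 4.30 on the other 4, Epor, the erythropoietin receptor gene, 6.01 against at most 4.26, and Slc25a37, a mitochondrial iron importer gene, 9.16 against at most 7.88. Tfr2 read 8.24, within their range. Without that array the list averaged -0.02 (adjusted p = 0.831, with the test's direction up). Within the 3 control and 3 other Jag1+/-Rfng+/- arrays with the shared sample-name number it averaged 0.21 (adjusted p = 0.00135). With the portal fibroblast covariate it averaged -0.01 (adjusted p = 0.970).

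**Figure D3:**
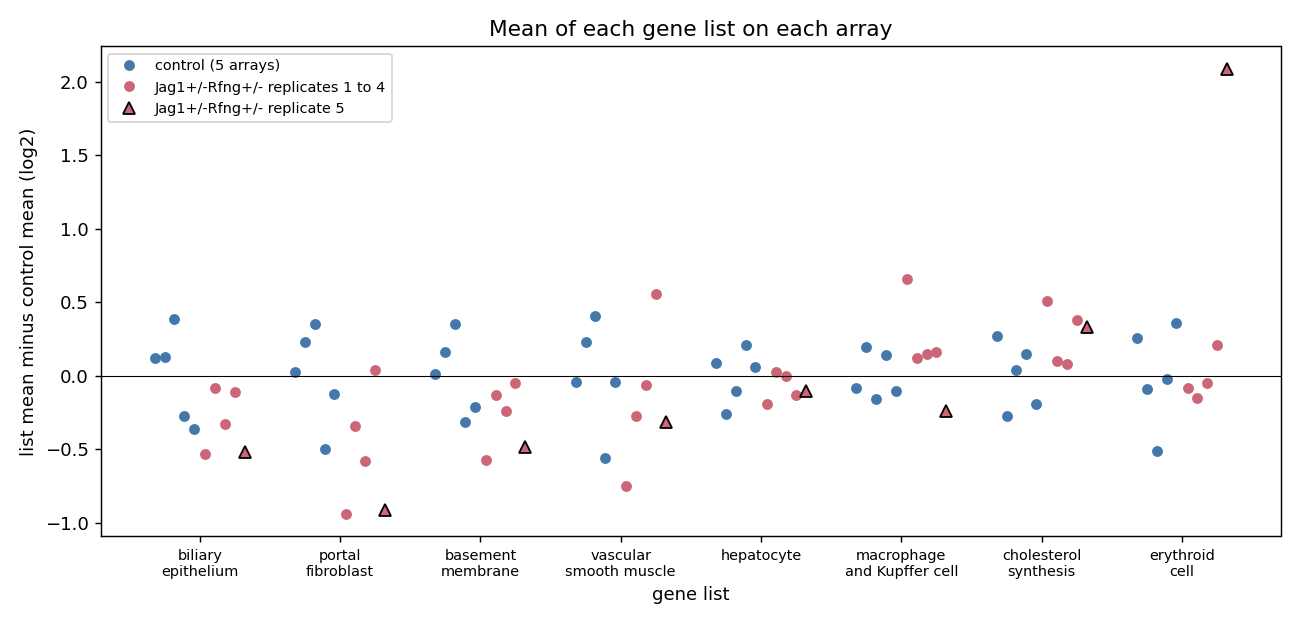
Mean of 8 gene lists on each array, as the difference from the mean of the 5 control arrays (vertical axis, log2); blue points are controls, red points Jag1+/-Rfng+/- replicates 1 to 4 and the outlined triangle replicate 5. The triangle lies at 2.09 for the erythroid list, and control replicates 4 and 5 lie below 0 for the biliary and portal fibroblast lists, at -0.27 and -0.36 and at -0.50 and -0.12.

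The other 23 lists did not pass the camera test, and the Notch targets given above make 24. Hepatocyte genes differed by a mean of -0.08 log2 (camera adjusted p = 0.201), pericentral hepatocyte genes by 0.06 (0.563) and fetal and early postnatal hepatocyte genes by -0.10 (0.452). Among other cell types of the tract or its surroundings, hepatic stellate cells gave 0.06 (0.417), vascular smooth muscle -0.17 (0.417), vessel endothelium -0.11 (0.269), sinusoidal endothelium 0.06 (0.125), lymphatic endothelium -0.02 (0.462), nerve and Schwann cells -0.09 (0.452), lymphocytes -0.16 (0.200) and megakaryocytes 0.02 (0.825, with a median of -0.05 and the test's direction up). Of the pathway lists, TGF-beta and BMP signalling gave -0.12 (0.0820), Wnt signalling 0.02 (0.825), YAP targets -0.15 (0.106), cell cycle -0.02 (0.564), bile acid synthesis and transport 0.11 (0.106), inflammatory response 0.00 (0.417), interferon-stimulated genes -0.13 (0.106), immediate early and heat shock genes 0.07 (0.286) and circadian clock genes -0.02 (0.565, with a median of 0.05 and the test's direction down). Ribosomal protein genes gave 0.00 (0.825), oxidative phosphorylation genes -0.03 (0.462) and pancreatic enzyme genes 0.00 (0.566). In fry's test for change in either direction the lymphocyte and circadian clock lists passed (adjusted p = 0.0292 each), besides the biliary list.

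Genes that neighbour the targeted loci did not stand out at the planned window size. Of the 100 tested genes nearest Jag1 on chromosome 2, 6 had an unadjusted p under 0.05, and a share of 0.67 of all windows of that many genes in the genome held as many. Of the 76 neighbours of Rfng, which lies near the end of chromosome 11, 8 did (10.5%), against 6.79% of all genes, and a share of 0.16 of equally large windows held as many. For Rfng the share of windows was 0.03 with 100 genes taken on either side (15 of 126 neighbours, 11.9%).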

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

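The tests of explanations in this part were chosen after the patterns, or values related to what they measure, were seen, except the count of splits for members of all lists together.

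In 202 sets of 5 arrays (65 genes, 35 list means and the median correlation, in each group), 12 held an array far from the other 4, where chance gives about 1 in 20 sets, or 10.1. Of these, 6 lay on Jag1+/-Rfng+/- replicate 5. Its median correlation with the other arrays was 0.959 (others 0.975 to 0.980). There Epor read 6.01 (others 4.14 to 4.26) and Add2 6.55 (others 3.77 to 4.30). The mean of the erythroid list there was 6.6 (others 4.36 to 4.72), that of the stellate cell list 5.83 (others 6.11 to 6.22) and that of the sinusoidal endothelium list 6.02 (others 6.31 to 6.42). Ctsg read 7.54 on Jag1+/-Rfng+/- replicate 3 (others 6.03 to 6.30). On Jag1+/-Rfng+/- replicate 2 the neutrophil and myeloid progenitor list averaged 6.26 (others 6.61 to 6.74) and the circadian list 5.05 (others 5.20 to 5.25). On control replicate 4 Eola1 read 4.67 (others 3.74 to 4.01) and the nerve and Schwann cell list averaged 3.67 (others 3.82 to 3.87). Mme read 4.58 on control replicate 5 (others 5.28 to 5.42), still above the Jag1+/-Rfng+/- arrays at 2.78 to 3.44.

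Jag1+/-Rfng+/- replicate 5 carried erythroid transcripts that the other arrays lacked at that level. It had the highest value of all 10 arrays for 84% of the erythroid genes (21 of 25), among them Slc4a1 at 10.04 and Slc25a37 at 9.16, against at most 7.79 and 7.88 elsewhere, while Tfr2 at 8.24 was not raised, a pattern consistent with blood-forming cells in the captured tissue as a hypothesis. The list shares 0 genes with the other lists, and 20 of its genes lie above the median gene in controls; livers of this age still hold blood-forming cells. Values compressed by weak or degraded RNA, taken as 1 slope over all genes, would give -2.79% of the measured rise. This argues against such even compression for the erythroid genes, while RNA loss that differs between transcripts was not tested. The slope of this array on the mean of the others, 0.943 against 0.992 to 1.015, is the lowest and leaves compression open for the rest of its difference. A wrong genotype label is argued against by Slpi and Mme, which pass without this array and lie at least 1.53 log2 outside the control range on it; whether genotype has a part cannot be tested on 1 array.

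The biliary genes that moved both ways were not the work of replicate 5 alone, since 9 members passed adjusted over the list alone without it, 8 of them among the 11. With the portal fibroblast list as covariate 9 biliary members passed, 6 of them among the 11. That count alone does not weigh against a smaller share of portal tissue in the capture. The covariate was itself lower in Jag1+/-Rfng+/-, and with it Cldn6, Cldn7 and Krt23 moved further up (2.01, 1.05 and 0.93 log2). A smaller share would lower portal genes together. Without the covariate Cldn6, Cldn7 and Krt23 were already higher (1.24, 0.80 and 0.77 log2). A smaller share is argued against as the whole cause only if these genes are expressed mainly in portal cells, which was not tested. It stays open for part of the lower genes, of which 3 of 8 passed with that covariate: the estimates of Krt7 (-0.75 ± 0.25 to -0.16 ± 0.18 log2, SE), Krt19 (-0.75 ± 0.23 to -0.35 ± 0.24), Epcam (-0.76 ± 0.28 to -0.25 ± 0.28), Prom1 (-0.71 ± 0.21 to -0.51 ± 0.26) and Onecut1 (-0.48 ± 0.16 to -0.30 ± 0.19) shrank, while Muc1, at -1.49 ± 0.34, still passed. The portal fibroblast mean alone did not pass the array-level test (exact permutation p = 0.0635, and 0.111 without replicate 5). Relative to the mean of the vessel endothelium and vascular smooth muscle lists it was lower by 0.41 log2 (control SD 0.09, Jag1+/-Rfng+/- SD 0.21, exact permutation p = 0.0159, two-sided). A smaller portal share would not give this only if it lowered all these lists alike. That was not tested, so the comparison cannot decide whether the portal share was smaller. The genotype and the size or position of the tracts captured remain open, and neither was tested.

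Slpi, Ehf, Ahcy and Itga6 lie on chromosome 2 with Jag1, with 302, 370, 178 and 777 tested genes between, and Krt23, Abcc3, Mpo and Gabrp on chromosome 11 with Rfng, with 421, 571, 616 and 1407. DNA of another strain carried along with a targeted allele may alter such genes, but a share of 0.67 of windows held as many low p values as the neighbours of Jag1, and 5.15% of chromosome 2 genes had a p under 0.05 against 6.79% of all. Around Rfng that share of windows was 0.16 with 50 genes on either side and 0.03 with 100, and 7.03% of chromosome 11 genes had a p under 0.05. A few altered genes would not raise these shares, so the explanation cannot be told apart from an effect of genotype for the genes on either chromosome; the strain of the Jag1+/-Rfng+/- mice is not given. For Ahcy, a candidate explanation is that its probe sets do not measure the same transcript, since the other probe set differed by -0.80 ± 0.25 log2 (SE) against 1.47 ± 0.20.

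Chance in how the arrays are grouped was tested with 100 splits. The 2 genes past the adjusted threshold were matched by 1 split, the real one (highest other 0), and the 11 biliary members by 1, the real one (highest other 9). For the count of genes on all 10 arrays this makes chance less likely but does not exclude it. Without replicate 5, 3 of 100 splits gave as many as the real 2 genes, and 2 of them gave more (highest other 4). The biliary count was singled out after its values were seen, as 1 of 7 such measures, so its split count weighs less against chance than it reads. Nor can chance be excluded for the 332 genes past the unadjusted p and fold, matched by 5 splits (highest other 461). The same holds for the 36 members past adjustment over their list alone in all lists together, matched by 5 (highest other 97). It also holds for the 11 lists called, matched by 44 (highest other 23). The split with 461 genes sets control replicates 1, 2 and 3 and Jag1+/-Rfng+/- replicates 2 and 4 against the rest, sides whose portal fibroblast means lie at 0.06 and -0.61. The split with 97 members likewise parts arrays at 0.11 and -0.65, which points to a structure among the arrays that runs with portal fibroblast content. Shares of low p near the targeted loci were matched by 29 splits for Jag1 (6%, highest other 14%) and by 6 for Rfng (10.5%, highest other 17.1%), so chance cannot be excluded there either.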

How the results depend on the processing

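All alternatives but 2 were chosen before the data were examined; those with the arrays of the shared sample-name number without Jag1+/-Rfng+/- replicate 5 and with the fibroblast covariate were added later. The cause of the changes below was not tested. Slpi and Mme passed with the same sign in all alternatives run for them but the 3 against 3 arrays with that number and no replicate 5 (2.16, adjusted p = 0.134, and -2.12, adjusted p = 0.0566), where limma called 0 genes and 1215 had an unadjusted p under 0.05. Other counts of genes past 0.05 were 2 to 6 on leaving out 1 array, 5 with array weights, 11 with trend and robust, 11 among genes above the median level, where fewer genes were tested, and 6 with the hepatocyte covariate.

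Leaving out 1 array gave Jag1 differences of -1.61 to -1.11, 9 to 19 lists (19 without control replicate 4, 17 without Jag1+/-Rfng+/- replicate 4), 5 to 13 biliary members and 7.9% to 14.5% of low p near Rfng (14.5% without Jag1+/-Rfng+/- replicate 1). The Rfng share was 13.2% with medians centred and 11.9% with 100 genes on either side, both now past 0.05 of windows. Rfng differed by -0.38 within the arrays with the shared number (exact permutation p = 0.0571). Biliary members past adjustment over the list alone numbered 4 in the arrays with the shared number and 6 there without replicate 5. Where a block, covariate, weights or another eBayes setting was used, the fit's unadjusted p of Jag1 and Rfng was compared with that of the fit without it (0.00819 and 0.00257), not with the exact permutation p given for them in the results.

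Camera passed 18 lists with the hepatocyte covariate, 0 with an estimated correlation and 7 with the portal fibroblast covariate, and fry's directional test 0. With the fibroblast covariate 7 lists turned direction: Notch receptors (0.02), Notch targets (0.06), biliary epithelium (0.02), erythroid (-0.01), fibrillar collagen and matrix (0.28), basement membrane (0.04) and fasting (-0.02), of which the matrix list passed (adjusted p = 1.49e-06), and the tubule and cilium (0.00) and macrophage (0.10) lists no longer passed. The covariate was itself lower in Jag1+/-Rfng+/-, and camera's preset correlation was used, so these turns are not read as rises or falls.

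The replicate numbers do not pair the arrays: correlations of same-numbered deviations were -0.23 to 0.06, and 0 of 5 control arrays correlated best with their own number. With a replicate block limma called 2 genes, 348 passed the unadjusted p and fold and 12 lists passed. No signal over background per probe was at hand, so folds of genes near the level of absent genes, such as Sucnr1, Ehf and Mme, cannot be bounded.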

Other observations

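The genes in this paragraph were chosen after their values were seen, from lists that did not pass the camera test, and the test of injury genes below was prompted by values already seen. In the bile acid list 4 of 34 members passed adjusted over the list alone, all higher in Jag1+/-Rfng+/-: Cyp27a1, a sterol hydroxylase of bile acid synthesis, 2.00-fold (6.05 ± 0.67 in controls, 7.05 ± 0.26, SD, n = 5 each), Baat, which conjugates bile acids, 1.96-fold, Abcc3, an efflux transporter, 1.80-fold, and Abcb4, the phospholipid exporter of bile, 1.51-fold. Stellate cell genes went both ways: the pericyte and mesenchymal genes Rgs5 and Tcf21 were 1.83-fold and 1.99-fold lower, and Gdf2 and Fcna 1.85-fold and 1.41-fold higher. Among endothelial genes Sox7, a transcription factor, was 1.56-fold lower, Adgrg6 2.01-fold lower and the sinusoidal scavenger receptor gene Stab2 1.34-fold higher. Further members past adjustment over their list alone were Scn7a (lower, with a Jag1+/-Rfng+/- mean of 2.64 within the range of absent genes), Cry1, a clock repressor gene (1.51-fold lower), Sema3d (1.51-fold lower), the lymphocyte genes Nkg7 and Cd2 (1.54-fold and 1.46-fold lower) and Blk (1.45-fold higher). The lymphocyte and circadian lists passed fry's test for change in either direction (adjusted p = 0.0292 each). None of these genes passed adjusted over all genes, where limma's adjusted p ranged from 0.176 to 0.561.

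Without Jag1+/-Rfng+/- replicate 5 the lists read differently. The macrophage and Kupffer cell list then lay higher in 26 of 26 members (mean 0.27, camera adjusted p = 2.96e-07), and cell cycle genes lay lower in 34 of 41 (mean -0.15, camera adjusted p = 0.000137). The bile acid list (0.16, camera adjusted p = 0.0165), the sinusoidal endothelium list (0.12, 0.0167) and the inflammatory list (0.12, 0.0167) lay higher. With an estimated correlation none of the 35 lists passed on these 9 arrays (lowest adjusted p = 0.639). Exact permutation of list means on them gave p = 0.103 for macrophages, 0.198 for cell cycle, 0.349 for bile acids, 0.278 for sinusoidal endothelium and 0.286 for inflammation. The 13 lists called there were matched by 34 of 100 splits, the real one included (highest other 23), so chance cannot be excluded. The macrophage mean was 0.66 above controls on Jag1+/-Rfng+/- replicate 1 and 0.12 to 0.16 on replicates 2 to 4.

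Slpi, Tff3, Tnfrsf12a and Abcc3 are genes whose expression can rise in injured or cholestatic liver, so a wider rise of such genes was tested as a hypothesis. A list of 17 further genes of that kind was written before their values were looked at, with members of the fixed lists and named genes left out. Its mean differed by -0.07 log2 between the groups (control SD 0.14, Jag1+/-Rfng+/- SD 0.10, exact permutation p = 0.357, two-sided), with 10 members higher and 7 lower. Tspan8, a tetraspanin gene in that list, differed by -1.42 ± 0.34 log2 (SE), and the other 16 genes averaged 0.01. The bound set beforehand, a difference under 0.1 log2, was met, which argues against a wider rise across these 17 genes. The largest rise among them was 0.26 log2 (Anxa5), against 0.85 for Abcc3 and 2.35 for Slpi. The list leaves out the genes that prompted it and members of the fixed lists, so the hypothesis stays open for those genes.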
